A study of Mus musculus with 7 samples.

How the data were processed

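Total RNA of 7 mouse samples was hybridized to 7 Agilent 4x44K one-colour arrays, and each sample formed a group of its own (1 array per group). Per the labels, the signal was extracted with Agilent Feature Extraction 10.5, while the file headers name version 10.7.3.1 for the ES-derived arrays and 10.5.1.1 for the other 5. Per the file headers, the scanner files hold each spot's background-corrected intensity and flags for control spots, outliers and signal well above background. The authors also deposited 1 table per sample in log2 units, scaled to the 75th percentile of the array. Its 41265 values per sample had medians of -3.33 (day 42), -2.92 (day 46), -2.75 (esophagus), -2.68 (lung), -2.86 (stomach), -2.98 (intestine) and -3.43 (embryonic stomach), and correlated with the values used here at 0.999 or above. No column of another sample was present in the files.

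Each array had 45018 spots, of which 43379 were not controls. Control spots and outliers (between 40 and 728 per array) were left out, and no spot was saturated. Spots of the same probe were averaged as log2 of the processed intensity, and the array's 75th percentile was subtracted. A probe counted as well above background where the scanner software's flag was set in at least 0.5 of its spots. Of 41174 probes, 24375 were named by accession and 57 by symbol or synonym in the reference table, which was used for names alone, and 16742 stayed unnamed and out of the analysis. The probe with the highest mean over the arrays stood for each of the 17047 genes, 5797 of which had several probes. In a comparison, a gene not well above background on 1 array took the higher of that array's lowest signal among probes above background and its own signal, which makes the fold a lower bound, and a gene not above background on either array was left out. Where this bound left the detected array no higher than the other, the difference was set to 0. Technical spread came from 245 probes with 10 spots (median standard deviation per array between 0.05 and 0.09) and from different probes of the same gene. The latter is the standard deviation between probes of the log2 difference, rescaled from pairs of probes to a single probe. It was 0.49 for day 46 against day 42 and 0.84 for each ES-derived array against adult stomach. For day 42 against embryonic stomach it was 0.86, and for embryonic against adult stomach 0.62.

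With 1 array per group no test was possible, and results are sizes, counts and ranks. Genes enriched in an adult organ were at least 8-fold higher there than in each of the other 3, and the share of each list above background has a Wilson 95% interval. Correlations are Spearman's, over genes above background on at least 1 array. The 5 comparisons between arrays count genes at least 4-fold higher or lower. For each of 42 gene lists the members at least 2-fold higher or lower were counted, and the median was placed among 10000 random lists of the same size matched on mean signal in 20 bins. List members were matched by current symbol, by an older symbol given in the list, or by a synonym that is not another gene's symbol. Muc6 and H19 had no named probe. Another 5 lists were added later for the tests in the closing section. Genes named in a comparison were the 8 with the largest and the 8 with the smallest difference among genes above background on both arrays, the 4 on each side with the largest bound, the 2 to 4 members of a list with the largest absolute difference, a fixed set of genes of stomach development and function, and the 5 highest genes of each organ list. Names that are clone or locus numbers were skipped, and text names fewer genes than the rule allows. The comparisons, lists, thresholds and naming rule were chosen before the data were examined.

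The alternatives were median centring, quantile normalization, the authors' table, another background correction (normexp of limma 3.58.1 with an offset of 50, on median signal and median local background, because the files carry no mean signal), no filter on background, only genes above background on every array compared, the mean over a gene's probes, Pearson's correlation, a 4-fold threshold in place of 8-fold for the organ lists, a 2-fold threshold in place of 4-fold for the counts, and, chosen after seeing the data, an equal number of genes above background on each array. A value counted as stable under an alternative where a count stayed within 1.5 times, a share within its Wilson interval, a correlation within 0.05, a list's median within 1 standard deviation of its medians over 1000 resamplings of members, and a named gene within the standard deviation between probes. The counting was tested on simulated data. The simulated array was built from the other array of the pair and shared its lowest signal above background. Genes were seeded only where that array's signal was not low. Differences between real arrays in background, slide or labelling were not simulated, so the rates for unchanged genes leave them out. With the spread between probes of the same gene as noise, 28 of 50 genes seeded at 2.25 (log2), 43 of 50 at 2.5 and 50 of 50 at 3.5 were counted for day 46 against day 42 (13454 genes), along with 17 of 50 at 1.75 and 1 of 13154 unchanged genes. For day 42 against adult stomach (14664 genes) these were 38, 38 and 48 of 50, with 17 of 50 at 1.75 and 268 of 14364 unchanged genes. Of 200 random lists, 10 fell outside the central 95% for day 46 against day 42 and 3 for day 42 against adult stomach. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 were used. Arrays that the study design mentions for day 46 without Shh and Bmp4 and for older tissue were not analysed here.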

Results

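Total RNA from 7 mouse samples was measured on 7 one-colour microarrays, 1 array per sample and 1 sample per group. The set held stomach-type tissue grown from embryonic stem (ES) cells at culture day 42, the same kind of culture at day 46, adult esophagus, lung, stomach and intestine, and stomach of embryonic day 9.5 (E9.5). The day 42 tissue had been kept in a medium containing EGF with the growth factors FGF10 and Wnt3a, the BMP inhibitor Noggin and the Wnt enhancer R-spondin1. The day 46 tissue had spent the 4 days after day 42 with the signalling proteins Shh and Bmp4, and the labels do not state which of the first factors were withdrawn. There were no replicates, so no test, error or p-value is given, and the number of arrays limits the precision of every value. The share of 17047 named genes well above background was 78.4% on the day 42 array, 90.6% on the day 46 array, 83.9% in esophagus, 78.7% in lung, 85.2% in stomach, 84.4% in intestine and 82.1% in embryonic stomach. Probes spotted several times on an array had a median standard deviation between 0.05 and 0.09 (log2). Values are log2 signals relative to the array's 75th percentile, and differences are log2 differences, where 1 stands for 2-fold. A fold given as "at least" belongs to a gene not well above background on the lower array. The 4 adult organs shared 1 slide and each of the other 3 samples lay on a slide of its own, so slide and sample group cannot be told apart outside the adult organs. Genes are not independent replicates, so counts, intervals and correlations across genes describe these arrays alone.

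The first comparison asked which adult organ's genes the ES-derived and embryonic tissues contained, using genes at least 8-fold higher in 1 adult organ than in each of the other 3. The 125 stomach-enriched genes were headed by the surface mucous peptide Tff1, the pepsinogen Pgc, the acid pump subunit Atp4b, Pla2g1b, a secreted phospholipase also made by the pancreas, and the gastrokine Gkn2, with normalized signals from 9.68 to 10.44 in adult stomach. Tff1 reached 4.36 in day 42 tissue and 6.19 in day 46 tissue, Gkn2 reached 0.84 and 7.23, and Pgc 2.06 and -1.48. Atp4b stayed at -4.84 and -3.87, and Pla2g1b at -5.54 and -5.74. In embryonic stomach Tff1 was at -4.26, and Gkn2 and Pgc were not well above background. The 362 intestine-enriched genes were led by the fatty acid carriers Fabp2 and Fabp1, the goblet cell lectin Zg16, the keratin Krt20 and the aminopeptidase Anpep. Zg16 was at -3.45 in day 42 tissue and 3.40 in day 46 tissue, and Krt20 at 1.04 and 5.88. The 189 esophagus-enriched genes were headed by the striated muscle genes Tnnc2, Tnni2, Myh8, Acta1 and Tcap, and held 13 of the 15 skeletal muscle genes fixed beforehand. The 253 lung-enriched genes were led by Sftpc, Scgb1a1, Cbr2, Inmt and Wfdc2. Sftpc, a surfactant protein, was not well above background on either ES-derived array, whereas the secreted inhibitor Wfdc2 reached 7.48 at day 42 and 6.44 at day 46.

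Of the stomach-enriched genes, 72.0% (Wilson 95% interval 63.6 to 79.1) were well above background in day 42 tissue, 90.4% (84.0 to 94.4) in day 46 tissue and 64.8% (56.1 to 72.6) in embryonic stomach. The intestine-enriched genes gave 76.2%, 91.4% and 64.6%, the esophagus-enriched genes 69.8%, 88.9% and 76.7%, and the lung-enriched genes 63.2%, 79.1% and 70.0%. No list exceeded the share of all genes on its array by more than its interval. The lung list lay below that share by more than its interval on all 3 arrays (at day 42, upper limit 68.9 against 78.4%), as did the esophagus list at day 42 (75.9) and the stomach (72.6) and intestine (69.4) lists in the embryo against 82.1%. With another background correction, under which the lung list held 114 genes, the lung shares were 78.9%, 90.4% and 81.6% and the esophagus share at day 42 was 78.9%, while the embryo's stomach (68.2%) and intestine (63.3%) shares stayed low. With no filter the lung shares were lower, at 53.4%, 70.2% and 58.9%. With an equal number of genes counted as above background on each array, an alternative chosen after seeing the data, the stomach share was 69.6% at day 42 (61.1 to 77.0) and 71.2% at day 46 (62.7 to 78.4), below the 78.6% of all genes counted. Every other share also had its upper limit below 78.6%, except that of the intestine list at day 42 (75.7%, upper limit 79.8). Genes of each list were chosen for being high in their own organ, which favours but does not force lower values on these 3 arrays. The choice did not use these arrays. The median difference to that organ at day 42, at day 46 and in embryonic stomach was -5.06, -4.66 and -7.04 for the stomach list, -4.13, -4.66 and -4.46 for lung, -5.07, -5.53 and -6.46 for esophagus, and -5.56, -5.64 and -7.45 for intestine.

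The closeness of whole profiles was compared by rank correlation across 15873 genes. Both ES-derived arrays were closer to each other (Spearman's rho 0.976) than to any other array. Among the adult organs, adult stomach was the closest to day 42 tissue (0.864, against 0.852 for lung, 0.849 for esophagus and 0.827 for intestine) and to day 46 tissue (0.862, against 0.846 for lung, 0.843 for esophagus and 0.829 for intestine). Embryonic stomach correlated at 0.792 with day 42 tissue and 0.786 with day 46 tissue. Its closest adult organ was esophagus (0.765), followed by lung (0.759), stomach (0.755) and intestine (0.696).

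**Figure D1:**
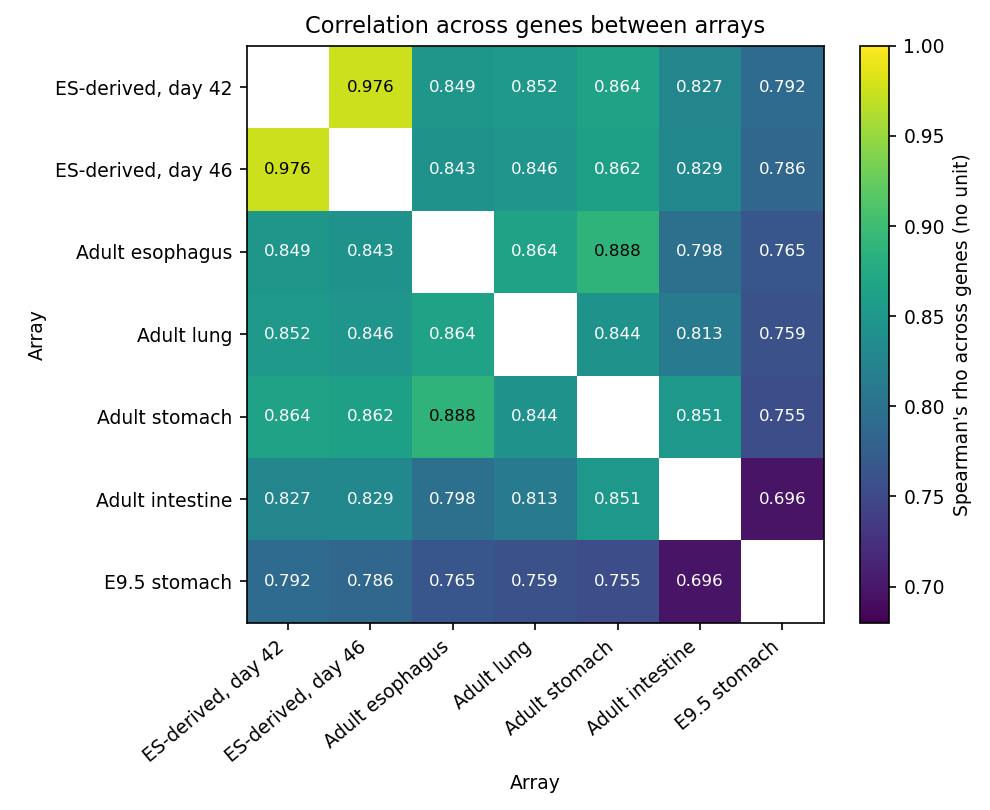
Spearman's rho across 15873 genes (no unit) for each pair of the 7 arrays, with arrays on both axes and the value printed in each cell. The 2 ES-derived arrays correlate at 0.976 with each other, and each has its highest adult organ value with stomach (0.864 and 0.862).

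The comparison of day 46 with day 42 tissue addressed what went with 4 days in Shh and Bmp4. Medium and time in culture differ together in it, and a day 46 culture left in the first medium was not analysed here. Genes of the gastric surface mucous lineage were higher at day 46: Gkn2 by 6.39, the gel-forming mucin Muc5ac by 3.61, Tff1 by 1.83, and Gkn1 at least 14.1-fold. The neck cell peptide Tff2 (-7.53), the water channel Aqp5 (-4.90) and the chief cell products Pgc (-3.54) and intrinsic factor, Cblif (-1.55), were lower. The largest differences on the higher side included the goblet cell products Clca1 (8.76) and Zg16 (6.85), the gut antibacterial protein Lypd8 (6.33) and Krt20 (4.83). The mucin-folding enzyme Agr2 (-7.31), the gut glutathione peroxidase Gpx2 (-4.93) and Spdef (-4.11), a transcription factor of goblet and other secretory cells, lay on the other side. Among targets of BMP signalling, Id3 was higher by 3.68, Smad6 by 2.87, Id1 by 2.10 and Smad7 by 2.01.

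The position of each list's median was set against 10000 random lists matched on mean signal, a description and not a test, with 0 the lowest percentile and 100 the highest. Of 10 surface mucous genes measured, 7 were at least 2-fold higher and 1, the gastrokine Gkn3 (-4.69), was lower, with a median of 2.24 at percentile 100. Of 4 neck cell genes, 3 were at least 2-fold lower (median -3.55, percentile 0), and of 8 chief cell genes, 4 were lower and none higher (median -0.37, percentile 4.29, within the central 95% of random lists). Parietal cell genes had a median of 0, the value set where a bound gives no fold, with Atp4a at -0.41 and Atp4b at 0.97. Over parietal genes above background on both arrays the median was -0.37. The intestinal epithelium list had 5 of 19 genes higher and 2 lower (median 0.43, percentile 97.8). Squamous epithelium genes, led by the envelope proteins Ivl (3.72), Sprr1a (3.15) and Lor (1.90), had 7 of 21 higher and 2 lower (median 0.46, percentile 99.1). These last 2 medians were 0.03 and 0.06 under median centring. Pan-epithelial genes had a median of 0.20, or -0.20 under median centring.

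Of 13 BMP targets, 6 were at least 2-fold higher and 1 lower (median 0.86, percentile 100), and the median was 0.46 under median centring and 0.49 with another background correction. None of 7 hedgehog targets measured differed 2-fold, with Gli1 at 0.97, Gli2 at 0.86 and the receptor Ptch1 at 0.35. Shh itself was not well above background on either array, and the gastric mesenchyme regulator Barx1 only on the day 46 array, with no measurable difference. Notch targets were higher in 4 of 6 (median 1.11, percentile 99.8, or 0.71 and 0.45 under the same alternatives), among them Heyl at 1.35 and Hes5 at 1.28. The interferon response list had 5 of 10 genes higher and none lower (median 1.02, percentile 100, or 0.63 and 0.76 under them), with Ifi44 at 1.98 and Ifit1 at 1.97. Immediate early and heat shock genes, which respond quickly to stimuli, were higher in 4 of 13 and lower in none (median 0.85, percentile 100, or 0.45 and 0.77 under them), with Ccn1 at 1.66 and Dusp1 at 1.25. Wnt target genes went both ways, with the stem cell receptor Lgr5 at -2.35 and Sp5 at -2.37 but Lef1 at 1.51. Cell cycle genes were lower in 12 of 24 and higher in none (median -1.01, percentile 0), including Ccnb1 at -1.76 and Aurka at -1.73. Mesothelial genes (4 of 7 lower, median -1.71, percentile 0) and cardiac muscle genes (4 of 10 lower, median -0.82, percentile 0.05) were also lower, with Upk3b at -2.50 and Myl2 at -2.91. Smooth muscle genes had a median of 0.42 at percentile 100, with Acta2 at 0.50 and Des at -0.95, and the median was 0.02 under median centring.

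Over 15453 genes, 160 were at least 4-fold higher and 118 at least 4-fold lower at day 46, and 93.8% of other probes for these genes went the same way. The higher genes made up 57.6% of this total, against 25.7% with median centring, 33.5% with quantile normalization, 45.1% with another background correction (55 higher and 67 lower) and 75.8% with no filter (500 higher and 160 lower), while median centring shifted the median of all genes to -0.39. For the 10 spike-in RNA probes, the unscaled log2 signal on the day 46 array minus the median of the other 6 arrays had a median of -2.93, with a range from -3.15 to 2.36 over probes.

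**Figure D2:**
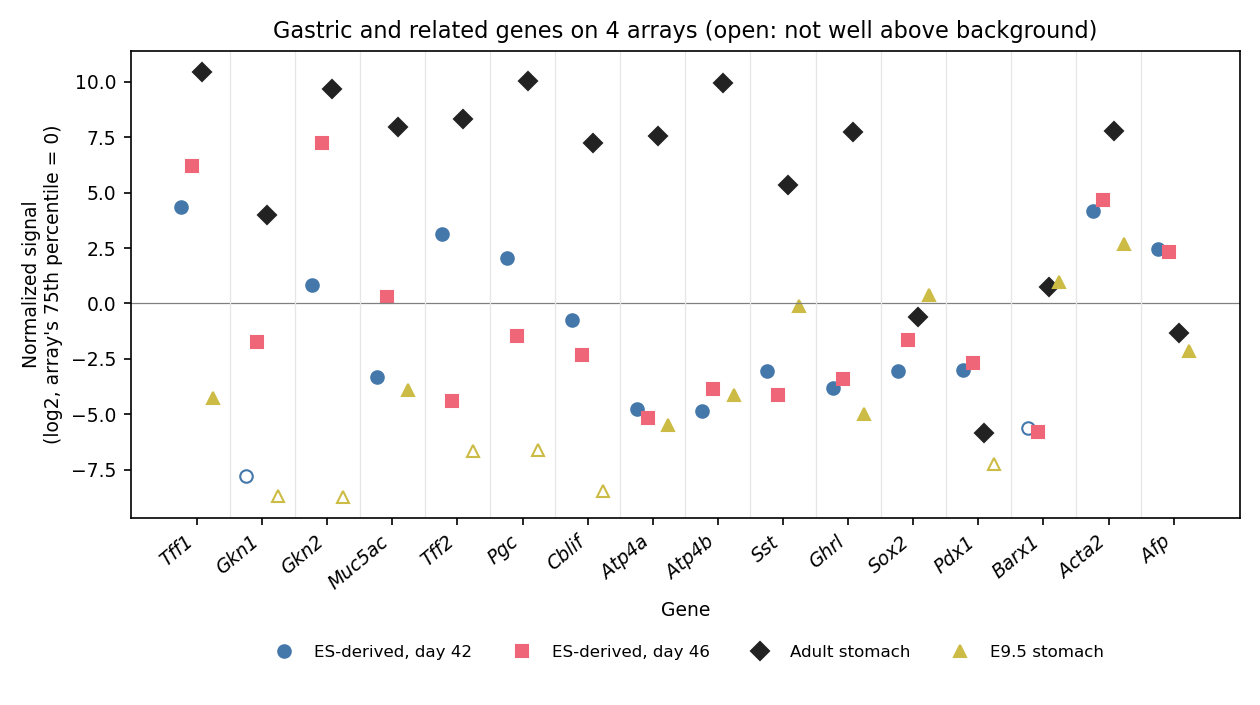
Normalized signal (log2, 75th percentile of each array at 0) of 16 genes on 4 arrays, where each marker is 1 array, open markers are not well above background, and heights are comparable within a gene and not between genes. Gkn2 goes from 0.84 at day 42 to 7.23 at day 46 against 9.68 in adult stomach, while Tff2 goes from 3.12 to -4.42.

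The comparison of day 42 tissue with adult stomach asked how tissue grown in the first medium differed from the organ. Genes of the differentiated gastric lineages were lower: Atp4b by -14.78 and Atp4a by -12.31 in parietal cells, Muc5ac by -11.27 and Tff1 by -6.09 in surface cells, Pgc by -7.99 in chief cells, and the hormones ghrelin (Ghrl, -11.55) and somatostatin (Sst, -8.42). The acidic chitinase Chia1 was at least 22736-fold lower and Barx1 at least 80.0-fold lower. The duodenal and antral transcription factor Pdx1 was higher by 2.84, and Sox2 was lower by -2.41. Plasma proteins of the liver were far higher in day 42 tissue, with the fibrinogen chains Fgg at 10.59 and Fgb at 10.37, albumin (Alb) at 8.03 and haptoglobin (Hp) at 9.09. Cardiac sarcomere genes were higher too, with Myh6 at 8.81 and Tnnt2 at 7.60, along with Nppa at 8.09 and Myom2 at 9.65.

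In this comparison 9 of 11 surface mucous genes were at least 2-fold lower and 1 higher (median -6.09, percentile 0), as were all 10 parietal genes (median -3.93, percentile 0) and 7 of 8 chief cell genes (median -5.75, percentile 0). The neck cell list had 3 of 4 lower, with Aqp5 on the other side at 7.70. Squamous genes, which line the mouse forestomach, were lower in 21 of 23 (median -4.68, percentile 0), with Krtdap at least 14406-fold lower and Lor at -11.16. Smooth muscle genes were lower in 10 of 11 (median -3.64, percentile 0), including Acta2 at -3.64, and endothelial genes in 10 of 12 (median -3.12, percentile 0), including Kdr at -5.76. Pancreatic acinar genes were lower in 10 of 14 (median -2.85, percentile 0), and adult stomach held the lipase cofactor Clps at a level of 10.13, Pnliprp1 at 3.95, Rnase1 at 2.08 and the trypsin gene Prss2 at 1.24. The hepatocyte list was higher in 11 of 13 (median 4.54, percentile 100) and the cardiac list in 8 of 10 (median 6.12, percentile 100). Macrophage genes were higher in 11 of 13 (median 2.02, percentile 100), with Marco at 8.59 and Cd14 at 3.66. Matrix genes such as Mmp2 (4.19) and Fn1 (4.11) were higher in 14 of 17 (median 1.79, percentile 100). Hypoxia and glycolysis genes were higher in 13 of 14 (median 2.93, percentile 100), with P4ha1 at 5.55 and Hk2 at 4.99. Fetal growth and imprinted genes were higher in 10 of 12 (median 2.59, percentile 100), led by Igf2 at 7.16. Cell cycle genes had a median of -0.38 at percentile 7.72, or 0.09 under median centring. Hox genes of groups 6 to 13 had a median of 0.33, which turned to -0.55 with another background correction, -1.56 over genes above background on both arrays and -0.052 with the mean over probes. Pou5f1 and Nanog, markers of pluripotent cells, were not well above background on either array.

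Of 14819 genes, 1095 were at least 4-fold higher and 1527 at least 4-fold lower in day 42 tissue, and 776 of 862 other probes for them went the same way. Median centring shifted the median of all genes to 0.43 and the share of higher genes among these calls from 41.8% to 61.6%, and the other background correction shifted the median to -0.15.

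The comparison of day 46 tissue with adult stomach asked the same of the tissue after Shh and Bmp4. Gkn2 lay closer to the organ, at -2.46, with Tff1 at -4.25, Gkn1 at -5.73 and Muc5ac at -7.66. Tff2 (-12.72), Pgc (-11.52), Atp4b (-13.81) and Atp4a (-12.72) lay far below it. The goblet cell products Zg16 (7.45) and Clca1 (6.93) were higher than in adult stomach. Fgb (9.66), Alb (8.45) and Myh6 (7.64) remained among the higher genes, and the growth factor binding protein Igfbp1 was at least 3611-fold higher.

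All 11 surface mucous genes were at least 2-fold lower than in adult stomach (median -4.25, percentile 0), as were 3 of 4 neck cell genes with 1 higher (median -6.43, percentile 0) and 9 of 10 parietal genes (median -4.15, percentile 0). Hepatocyte genes were higher in 11 of 13 (median 4.25, percentile 100) and cardiac genes in 8 of 10 (median 4.83, percentile 100). Immediate early genes were higher in 9 of 13 (median 1.41, percentile 100), with Ccn1 at 3.90 and Dusp1 at 2.97. Cell cycle genes were lower in 19 of 24 (median -1.60, percentile 0), with Top2a at -2.52. The 1079 genes at least 4-fold higher and 1559 at least 4-fold lower came from 15727, and 89.5% of other probes for them went the same way. The other background correction shifted the median of all genes to -0.16.

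**Figure D3:**
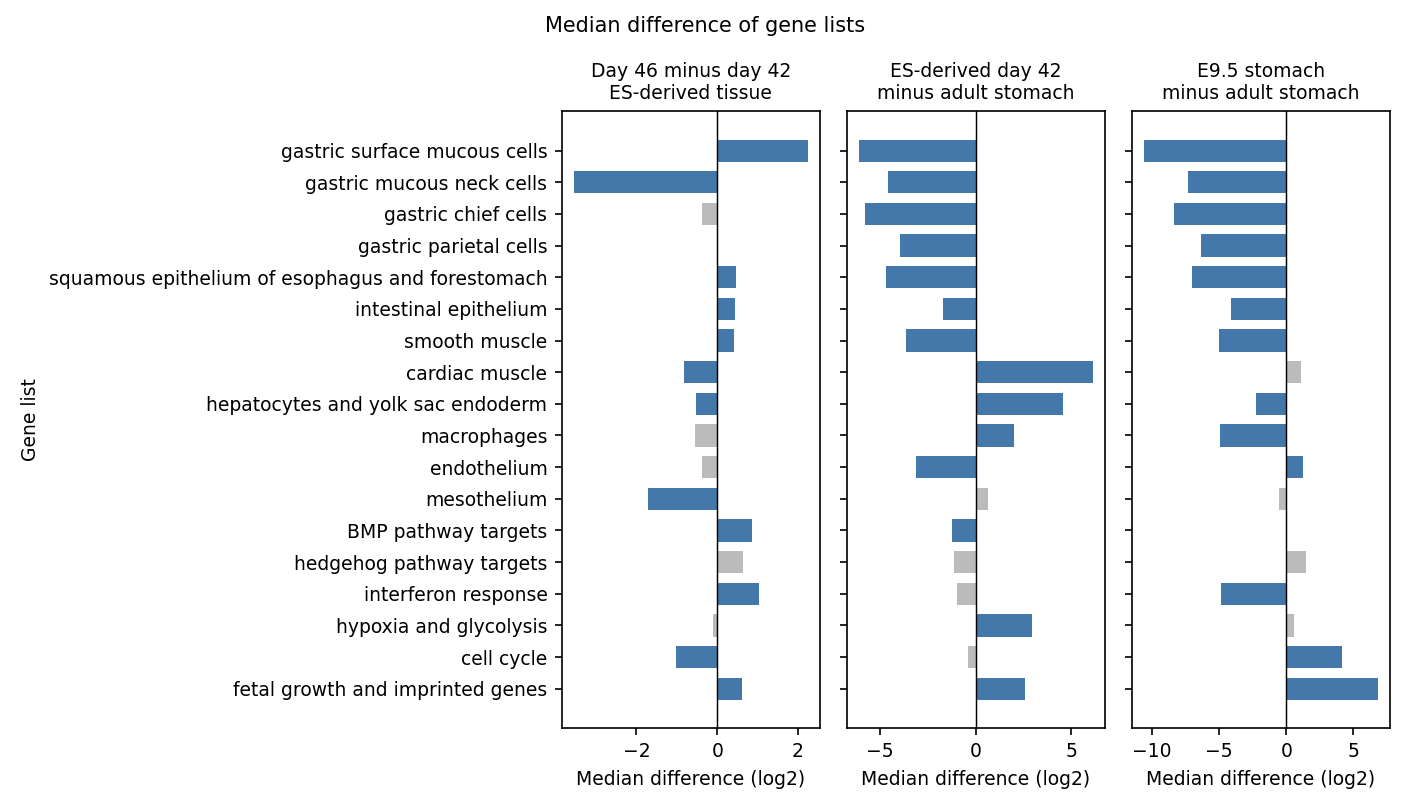
Median log2 difference (horizontal axis, on a scale of its own in each panel) of 18 gene lists (vertical axis) in 3 comparisons, with bars in blue where the median lies outside the central 95% of random lists and in grey elsewhere. The surface mucous bar is at 2.24 for day 46 against day 42 and at -6.09 for day 42 against adult stomach, and the cardiac muscle bar is at 6.12 in the latter.

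The comparison of day 42 tissue with embryonic stomach set the culture against the organ's primordium. Secreted and epithelial genes were higher in the culture: Tff1 by 8.61, Tff2 at least 751-fold, Pgc at least 360-fold and Agr2 at least 9487-fold, with the mucosal defence genes Dmbt1 (12.21) and Lyz1 (12.02). Among regulators fixed beforehand, Barx1 was at least 93.5-fold and Shh at least 32.2-fold lower, with Ptch1 at -4.59, Sox2 at -3.41 and Gli1 at -1.98, while Pdx1 was at least 10.9-fold higher. The embryonic globins Hbb-y (-11.73) and Hbb-bh1 (at least 5462-fold lower) and the Notch target Hes5 (-8.47) were lower as well. Macrophage genes were higher in all 13 measured, with Lyz2 at 12.10 and Marco at 10.82.

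Of 18 pan-epithelial genes, 16 were at least 2-fold higher in the culture (median 3.71, percentile 100), including Cdh1 at 5.35, and 11 of 15 stomach epithelial transcription factors were higher and 1 lower (median 3.44, percentile 100), with Elf3 at 6.71. Stomach mesenchyme factors were lower in 8 of 12 (median -2.05, percentile 0.06), with Isl1 at -4.00. Hedgehog targets were lower in 6 of 7 (median -1.98, percentile 2.21). All 24 cell cycle genes were lower (median -4.64, percentile 0), among them Top2a at -6.06. Interferon response genes were higher in all 10 (median 3.63, percentile 100) and antigen presentation genes in all 8 measured (median 4.46, percentile 100). Endothelial genes were lower in 9 of 12 (median -4.33, percentile 0) and erythroid genes in 9 of 10 (median -5.62, percentile 0). Genes of neurons and glia were lower in 9 of 14 and higher in 1 (median -2.26, percentile 0), and Hox genes of groups 1 to 5 in 13 of 15 (median -4.44, percentile 0). Of 14695 genes, 2506 were at least 4-fold higher and 1687 at least 4-fold lower, and 95.1% of other probes for them went the same way. The median of all genes moved to -0.13 under median centring and to -0.15 with the other background correction.

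The comparison of embryonic with adult stomach gave the reference for development of the organ itself. Differentiated gastric genes were lower in the embryo, with Tff1 at -14.70, Atp4b at -14.09, Pgc at least 91336-fold and Gkn2 at least 71178-fold lower. The fetal genes Mest (9.26), Hmga2 (7.36) and Lin28b (at least 552-fold) and the embryonic globin Hbb-y (10.02) were higher. Barx1 (0.22), Shh (0.05) and Bmp4 (0.15) were close to their adult levels, while Gli1 (1.43), Ptch1 (2.33) and Sox2 (1.00) were higher. The transcription factor Zic1 of dorsal neural tube and somites was at least 1394-fold higher, and Hoxb9, a trunk patterning gene, was higher by 7.83.

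All 24 cell cycle genes were at least 2-fold higher in the embryo (median 4.15, percentile 100), as were 12 of 13 fetal growth and imprinted genes (median 6.83, percentile 100), 12 of 15 Hox genes of groups 1 to 5 (median 3.16, percentile 100) and 13 of 17 of groups 6 to 13 (median 2.38, percentile 100), with 1 lower. Genes of neurons and glia were higher in 9 of 15 and lower in 4 (median 1.56, percentile 99.8), with Nes at 3.84 and Elavl4 at 3.47. Erythroid genes were higher in 7 of 10 (median 3.14, percentile 100). Smooth muscle genes were lower in 10 of 11 (median -5.05, percentile 0), with Myh11 at -9.34, and pan-epithelial genes in 13 of 18 and higher in 3 (median -3.44, percentile 0), with Krt19 at -6.38. Pancreatic acinar genes were lower in 11 of 14 and higher in 2 (median -4.01, percentile 0), with Clps at -14.75. Macrophage genes were lower in all 13 (median -4.94, percentile 0), antigen presentation genes in all 10 (median -5.66, percentile 0) and interferon response genes in all 10 (median -4.89, percentile 0). Of 15090 genes, 1736 were at least 4-fold higher and 2738 at least 4-fold lower, and 97.6% of other probes for them went the same way. Median centring shifted the median of all genes to 0.54 and the share of higher genes from 38.8% to 57.4%, quantile normalization shifted the median to 0.17, and the other background correction to -0.17.

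Finally, the day 46 minus day 42 differences were set against the adult minus embryonic stomach differences, which share no array, to ask whether genes of stomach maturation moved with Shh and Bmp4. Across 14634 genes Spearman's rho was 0.046. Of 2622 genes at least 4-fold higher in adult than in embryonic stomach, such as Tff1 and Gkn2, 43.1% (Wilson 95% interval 41.2 to 45.0) were higher at day 46 than at day 42. Of 1658 genes at least 4-fold lower in adult stomach, 40.7% (38.3 to 43.0) were higher at day 46. Among all 14634 genes 44.0% were higher at day 46. Genes whose difference was set to 0 count as not higher in these shares, so the remainder is not all lower. The shares of genes higher in adult stomach, lower in it and of all genes were 28.7%, 20.8% and 25.0% with median centring, and 38.5%, 31.3% and 38.5% with the other background correction.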

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

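The test of the slide and scanner software for the cardiac and hepatocyte genes and the test of epithelium loss at day 46 were chosen after the results were seen, and the other tests before. The control probes for spike-in RNA, which no comparison uses, stood out on the day 46 array. Over 10 probes, the unscaled log2 signal minus the median of the other 6 arrays had a median of -2.93 and a range from -3.15 to 2.36. Relative to each array's 75th percentile, the median spike-in signal was -2.93 at day 46 and between 0.73 and 2.15 on the others. What led to it was not tested.

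Cardiac and hepatocyte genes were higher in day 42 tissue than in adult stomach, with list medians of 6.12 and 4.54. The 16 lists of other cell types, gastric and pan-epithelial lists aside, had a median of medians of -1.44 (standard deviation between lists 1.87). Of these, 3 lists were above 0, with 2.02 the highest, so the lists were not raised as a whole. This cannot exclude a slide or scanner software difference raising tissue-restricted genes in general. Several lists are of cell types that adult stomach contains, such as squamous (-4.68), smooth muscle (-3.64) and endothelial genes (-3.12). Their medians can be low with or without such a difference. A slide difference limited to the cardiac and hepatocyte genes cannot be told apart from the groups either, because slide follows group. A further list of 10 cardiac genes, 8 of them also above background in adult stomach and none in another list, had a median of 2.13. Of these, 6 were at least 2-fold higher, while Pln (0.94), Casq2 (0.12), Hand2 (-0.32) and Ldb3 (-0.57) were not. Levels in day 42 tissue were 1.41 (Hspb7), 0.77 (Actn2) and 0.21 (Ttn), each higher in adult esophagus (2.51, 5.33 and 6.29). All other members were below 0 in day 42 tissue, though heights are not comparable between genes. Of them, Nppb (-1.17), Hand2 (-1.14), Pln (-1.36) and Tbx20 (-2.81) lay above adult esophagus, and Myoz2, Casq2 and Ldb3 below it. Nppb lay above every tissue array, with esophagus (-3.11) the highest of those, whereas Tbx20 lay below embryonic stomach (-2.26). Cardiac muscle cells in the culture are a candidate source, though these levels do not single them out. For hepatocyte-type cells the further list had a median of -0.00061 over 11 genes, 10 of its members also being above background in adult stomach, with Itih3 (level 3.13), F2 (2.11) and F10 (1.39) higher and Fetub (2.37) lower than in adult stomach. The criterion set beforehand for hepatocyte-type cells, a median at least 2-fold higher, was therefore not met. Because the members went both ways, this outcome was not used to decide, a rule that was not stated beforehand. Hepatocyte-type cells and liver genes active in other cells are thus not told apart here.

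Surface mucous genes were higher in 7 of 10 and neck cell genes lower in 3 of 4 at day 46 than at day 42, while 4 of 8 chief cell genes were lower with a list median (-0.37) within the central 95% of random lists. A constant scaling shift cancels in the difference between list medians. Other scaling and background differences were checked on the genes that define the pattern, so the check shows only how far processing changes it. Under quantile normalization, over genes above background on both arrays, the surface mucous median (2.62, 8 genes) still exceeded the pooled neck and chief median (-1.24, 10 genes) by 3.86. Over all measured genes, the neck list was then at -3.97 and the chief list at -0.43. With another background correction, the surface mucous, neck and chief medians were 2.15, -2.98 and -0.51. Loss of epithelium as a whole is argued against by a pan-epithelial median of 0.20, or -0.20 under median centring. The Shh and Bmp4 medium and the 4 further days of culture stay open as biological explanations, untested, since they change together, and slide is confounded with them.

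Trunk patterning genes were higher in the embryonic than in the adult stomach array. Somite genes had a median of 3.31 (8 of 10 higher, 1 lower, 6 also above background in adult stomach), with levels in the embryo of 2.01 (Foxc2) and 0.10 (Pax3). The lower gene was Tbx6 (-1.08), and Myf5 was not above background on either array. Neural tube genes had a median of 2.74 (10 of 14 higher, 11 also above background in adult stomach), with levels of 2.33 (Nkx6-1) and 0.75 (Isl2). Sox1 (-0.39), Neurog1 (-0.56), Evx1 (-0.11) and Lhx3 (0.65) were not 2-fold higher, and Lmx1a was not above background on either array. Somite and neural tube tissue in the dissected primordium are therefore candidate sources. A general excess of developmental regulators cannot be told apart from these, because only 3 of 8 forebrain and eye genes could be measured (median 2.92). That median meets the criterion set beforehand for such an excess, at least 2-fold higher. So short a list was not used to decide, a rule that was not stated beforehand.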

How the results depend on the processing

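The alternative with an equal number of genes above background on each array was chosen after seeing the data, and the others before. Each value was counted once per alternative. Of the values that answer the comparisons, 282 stayed within the bounds given in the processing section and 63 did not. Of 1462 list medians, 60 changed sign. Of these, 7 were among the 857 for lists outside the central 95% of random lists and 53 among the 605 for the others. By the bounds, 1336 list medians stayed. For named genes, 5761 values stayed and 823 moved, and 1 with a difference of at least 1 (log2) changed sign. Of those that stayed, 974 under median centring and 742 under the filter on all arrays compared could not have moved. Median centring shifts all genes of a comparison by a constant below the bound, and the filter leaves a gene's difference unchanged. Another 970 came from the authors' table, whose values are nearly the same. The total is therefore no measure of stability. Sign changes of smaller named gene differences were not counted separately. With the authors' table all 44 values and all 210 list medians stayed within these bounds, with a largest shift of 0.55 (log2), and with Pearson's correlation all 15. Adult stomach was the adult organ closest to both ES-derived arrays, and esophagus the closest to embryonic stomach, under each alternative that gives correlations. Median centring and quantile normalization leave the order of genes within an array nearly unchanged, and the authors' table holds nearly the same values. A rank correlation could hardly change under them, so only the other alternatives bear on this ranking. Except where a threshold was lowered, which by construction raises the counts, the cause was not tested.

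With the other background correction the lung list held 114 genes (253 before). Shares above background were 78.9% and 83.5% for the esophagus list (day 42, embryo), 78.9%, 90.4% and 81.6% for the lung list (day 42, day 46, embryo) and 81.2% for the stomach list (day 42). Counts were 55 higher and 67 lower for day 46 against day 42, 673 and 1009 for day 42 against adult stomach, and 570 higher for day 46 against adult stomach. Shares higher at day 46 were 38.5% and 31.3% of genes higher and lower in adult than in embryonic stomach. The Hox 6 to 13 median for day 42 against adult stomach was -0.55 (0.33 before).

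With no filter the shares were 62.6% for the esophagus list (day 42), 53.4%, 70.2% and 58.9% for the lung list (day 42, day 46, embryo) and 62.4% and 81.9% for the stomach list (day 42, day 46). The count for day 46 against day 42 was 500 higher, and shares higher at day 46 were 48.5% and 44.6%. With 4-fold in place of 8-fold the lists held 349 (esophagus), 559 (lung), 241 (stomach) and 669 (intestine) genes, and shares were 84.8% for lung (day 46) and 81.5% and 72.2% for intestine (day 42, embryo). With equal numbers of genes the day 46 shares were 67.7% (esophagus), 57.3% (lung), 71.2% (stomach) and 74.3% (intestine), and the embryo's were 55.2% (stomach) and 56.1% (intestine).

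Over genes above background on all arrays compared, the embryo correlated at 0.694 (esophagus), 0.666 (lung), 0.687 (stomach), 0.605 (intestine), 0.713 (day 42) and 0.702 (day 46). Hox 6 to 13 genes were at -1.56 for day 42 against adult stomach, and mesothelial genes at 0.090 (-1.47 before) for day 46 against adult stomach. Shares above background are fixed at their maximum by this filter and are not given.

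With median centring, counts were 83 higher and 240 lower for day 46 against day 42, 1716 higher for day 42 and 2880 higher for embryonic against adult stomach. Shares higher at day 46 were 28.7% and 20.8%. Pan-epithelial genes for day 46 against day 42 were at -0.20 and matrix genes at -0.23. With quantile normalization day 46 against day 42 gave 94 higher and 187 lower, and 34.3% of genes lower in adult stomach were higher at day 46. With 2-fold in place of 4-fold, counts higher and lower were 1390 and 1000 (day 46 against day 42), 2988 and 3356 (day 42 against adult stomach), 3050 and 3481 (day 46 against adult stomach), 4134 and 3803 (day 42 against embryo), and 4119 and 4490 (embryo against adult stomach).

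With the mean over probes, shares higher at day 46 were 45.2% and 44.2%, matrix genes for day 46 against day 42 were at -0.049, and for day 42 against adult stomach Hox 6 to 13 genes were at -0.052 and Btg2 at -0.10 (1.55 before). No paired analysis was possible because each group has 1 array, and no slide term because slides follow the groups. Signal over background limits which genes can be compared, as 78.4% of genes were above background on the day 42 array and 90.6% on the day 46 array.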

Other observations

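No test is reported in this part. Genes much higher in the ES-derived tissue than in any tissue measured were headed by the growth factor binding protein Igfbp1, at least 221-fold above each of the 5 other arrays on both ES-derived arrays. The vasoactive peptide gene Uts2 (5.59 log2 at the least), the acute phase inhibitor Serpina3n (5.53), the thyroid hormone deiodinase Dio3 (5.36), the collagen crosslinking enzyme Lox (5.24) and the plasma proteins Ahsg (5.08) and Alb (5.00) followed, along with the lens crystallin Cryaa (4.96) and the eye patterning factor Vax2 (4.62). In all 55 of 13165 genes were at least 8-fold above all 5 tissues on both arrays. These included 4 of 12 genes of the hepatocyte list, where 0.05 would be expected if genes were drawn evenly. This set was defined after the data were seen.

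Sex-linked genes separated the samples. Xist, transcribed from the inactive X chromosome, was well above background in esophagus (1.12), lung (0.37), stomach (0.45), intestine (-1.01) and embryonic stomach (-1.02), and not on the ES-derived arrays. The Y-linked genes Ddx3y and Eif2s3y were above background in day 42 tissue (-1.64 and -0.56), day 46 tissue (-1.83 and -0.26) and embryonic stomach (-0.57 and -0.95), and not in the adult organs. The Y-linked genes Kdm5d and Uty differed from these, as neither was above background at day 42 and both lay near the lowest measurable signals at day 46 (-6.51 and -6.57), against -1.69 and -4.65 in embryonic stomach. Embryonic stomach thus had transcripts of both kinds.

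Of 12 genes often used as a reference, 2 were at least 2-fold higher in day 42 tissue than in adult stomach, Eef2 (1.90) and Gapdh (1.63), and 2 lower, Actb (-4.73) and Ppia (-2.39). The list's median was 0.47 at percentile 86.5.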
